A study of Mus musculus with 2 samples.

How the data were processed

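Single-cell RNA of mouse corneal epithelium was measured with the 10x Genomics Chromium Next GEM 3′ v3.1 chemistry in 2 libraries, 1 from young C57BL/6J mice (11 weeks) and 1 from old mice (18 months). Each library pooled 4 corneas from 2 mice, whose epithelium was lifted with an enzyme and then dissociated with trypsin, per the labels' protocols. The submitters' processing notes name Cell Ranger 5.0.0, Seurat 4 and the genome build mm10. The annotation used for counting, the filters on cells and the handling of doublets and of free RNA are not given in the sources used here. The authors deposited a table of UMI counts (molecules counted once by their unique molecular identifier) per gene and cell, not normalized, and a metadata table whose other columns give each cell's age group and the authors' class. The authors' 8 classes are Basal, Wing, TAC1, TAC2, Squam, Conj, LSC and Immune. They were used under these deposited names, and the first 7 together are called epithelial here.

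The count table held 17437 genes and 21669 cells, and every cell in it was used. A cell's library was taken from the age column of the metadata. Counts were summed per library and class and given as CPM, the counts scaled to a common total of summed UMIs. With 1 library per age there is no replicate, so no test was run and no p-value or standard error is given. Ratios carry exact 95% conditional (Clopper-Pearson) intervals, shares carry exact 95% binomial (Clopper-Pearson) intervals, and differences between shares carry intervals built from these by the square-and-add method. These intervals, and the floor of 3 counts that stands for a count of 0, cover counting error only. Spread between mice, between corneas and between runs is not in them. Intervals of ratios of gene counts take each UMI as an independent draw, so spread between cells is not in them either. They are too narrow where few cells hold most UMIs of a gene.

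For the comparison over all cells, genes with at least 20 CPM in either library were compared by the ratio of CPM, with no pseudocount. For the comparison within classes, the log2 ratio of class CPM, with 1 CPM added, was averaged over the 7 epithelial classes with equal weight, each of which held at least 100 cells in both libraries. Genes at least 2-fold apart were counted in each comparison. The genes named are the 12 per direction and comparison, among genes of at least 50 CPM in either library, whose interval bound nearest 1 lay farthest from 1, and within classes also with 1 direction in every class used. Gene symbols made of Gm and a number, ending in Rik or starting with mt- were left out of this rule. For each gene list up to 4 members with the bound farthest from 1 and up to 2 nearest 1 could be named. The value of 1 list member that this rule allowed to be named is not reported here. Genes named outside the rule are said to be so and were chosen after their values were seen.

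The rule, 42 gene lists and 15 sets of cell type markers were fixed before the data were examined. A list with 4 or more measured members was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, drawn from the same 20 bins of mean expression. A member was counted as higher or lower at 1.25-fold, and members under 20 CPM in both libraries entered neither medians nor counts. The ribosomal list was taken by name pattern and also holds kinases named Rps6k. Reads could have been split between near-identical copies of Hspa1a, Cyp2a5, Cstdc5 and Krt6a in the authors' counting, so their values are uncertain. The cycling share is the share of epithelial cells with at least 2 of 9 cell cycle markers (Mki67, Top2a, Birc5, Ube2c, Cdk1, Cenpf, Tpx2, Ccnb1 and Ccna2). For this share and for shares of cells with a UMI, each cell was thinned to 5759 UMIs, which left out 1091 young and 981 old epithelial cells that held fewer.

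The 2 libraries were also clustered from their counts with the Leiden method (igraph 0.11.9), on 2000 variable genes, 30 principal components and 15 neighbours, at resolutions 0.5 and 1.0. Each such cluster was given the class that most of its cells carried in the authors' metadata. A further clustering left out 5140 genes that lay at least 1.25-fold apart between the libraries. Doublets were sought with the Scrublet score in scanpy 1.11.5 at an expected rate of 8%. Its automatic call marked 0.00872% of young and 0.00980% of old cells, so it had not worked, and the repeat without called doublets was not run. In its place the 8% of cells with the highest score were left out, which kept 10552 young and 9383 old cells.

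The settings fixed as repeats were trimmed-mean scaling (edgeR 4.0.16), median-of-ratios scaling (DESeq2 1.42.0), a total without mitochondrial, ribosomal and the 50 most abundant genes, minimum levels of 5 and 50 CPM, and a pseudocount of 5 CPM. Others were thinned cells, the mean of per-cell CPM, cells with at least 1000 UMIs and at most 10% mitochondrial UMIs (11399 young and 10142 old cells), own clusters, another denominator for the shares and other marker counts for cycling. Repeats without high Scrublet scores, without the Conj class, without a cluster of young cells alone, with clusters made without the genes apart, and with a ribosomal list without the kinases were chosen after seeing the data. Median-of-ratios scaling moved the median log2 ratio of all genes by -0.051 and trimmed-mean scaling by -0.047.

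The scripts were tested on simulated counts of the measured genes. For all cells, 100% of 50 genes set 2.5-fold apart and of 50 set 4-fold apart were counted as 2-fold, against 0% of 50 genes set 1.25-fold and of 50 set 1.5-fold apart and 0% of 4639 unchanged genes. Within epithelial classes the shares were the same, 100% at 2.5-fold and at 4-fold and 0% at 1.25-fold, at 1.5-fold and for the 4639 unchanged genes. The 95% intervals held the true ratio for 94.7% of 4839 genes, and 7.5% of 200 random lists of 10 unchanged genes lay outside the central 95%. The simulated counts had no spread between cells and no genes that move together, so these checks cover neither. Coordinates are from GENCODE annotation of mouse build GRCm38 (mm10), in which 46 of 47 genes looked up were found. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3.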

Results

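The study measured the RNA of single corneal epithelial cells from young mice (11 weeks) and old mice (18 months), 1 library per age. The young library held 11470 cells and 186175140 UMIs, with a median of 13500.5 UMIs and 2923.5 genes per cell. The old library held 10199 cells and 150472416 UMIs, with medians of 11994 UMIs and 2772 genes. The median depth of the old library was 0.888 times that of the young library. Its median share of mitochondrial UMIs per cell was 1.83%, against 1.56% in the young library. Because each age had 1 library, no difference below could be set against a spread between replicates, and the intervals hold counting error only.

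The first comparison asked which classes of cells the corneal epithelium held at each age. Basal cells made up 25.7% of the young library (2942 cells) and 31.0% of the old library (3164 cells), a difference of 5.37 percentage points (95% interval 4.16 to 6.58). Conj cells made up 9.30% of the young library (1067 cells) and 5.56% of the old library (567 cells), a difference of -3.74 points (-4.44 to -3.04). LSC cells made up 3.18% (365 cells) and 4.38% (447 cells), a difference of 1.20 points (0.685 to 1.72). Wing cells made up 25.9% and 24.0%, a difference of -1.91 points (-3.06 to -0.744).

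For the Squam class (13.0% and 12.6%), the TAC1 class (13.9% and 14.1%), the TAC2 class (8.46% and 7.92%) and the Immune class (0.567% and 0.412%) the interval of the difference held 0. Genes that mark the Basal, Wing, Conj, LSC and Squam classes themselves lay apart between the libraries. Clusters made without the genes that lay apart gave differences of 6.60 points for Basal, -2.61 for Conj, 2.62 for LSC, -3.87 for Wing and -1.78 for Squam. Clusters made with all genes turned the Wing difference to 0.70 points. A cluster of 191 young cells and 0 old cells, of which 130 were Conj cells, was found in the young library, and without it the Conj difference was -2.75 points.

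**Figure D1:**
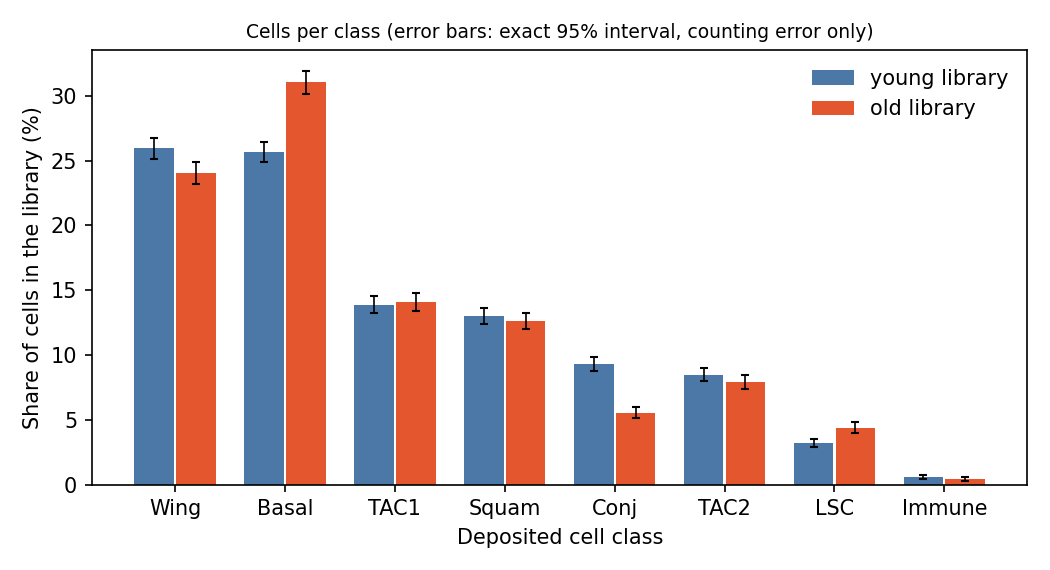
Share of the cells of each library (percent) in each of the authors' classes, for the young and the old library, with exact 95% binomial intervals. Basal cells took 25.7% of the young and 31.0% of the old library, and Conj cells 9.30% and 5.56%.

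The second comparison asked which genes were higher or lower in the old library over all cells. Among the genes farthest apart were the keratins Krt16 and Krt4, both lower in the old library. Krt16, a keratin of stressed and fast-growing epithelium, was at 221 CPM in the young and 7.13 CPM in the old library, 31.0-fold lower in old (29.1 to 32.9). Krt4, a keratin of mucosal epithelia, was at 518 and 96.7 CPM, 5.36-fold lower (5.27 to 5.45). Sprr1a, a small proline-rich protein of the cornified envelope, was 2.66-fold lower, at 54.6 and 20.5 CPM. The cluster of young cells alone held 76.5% of the young library's Krt16 UMIs, and without it Krt16 was 7.48-fold lower (7.02 to 7.97), Krt4 5.15-fold lower and Sprr1a 1.03-fold lower, with an interval that held 1 (0.982 to 1.08).

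Other genes lower in the old library by the naming rule were Crct1 (3.21-fold, 61.7 and 19.2 CPM), AA467197 (3.06-fold, 246 and 80.3 CPM), Ifit1bl1 (2.71-fold), Lce3a (2.53-fold), S100a7a (2.46-fold), Hspa1a (2.17-fold), Cyp2a5 (2.04-fold), Adh6a (2.00-fold) and Krt7 (1.999-fold). With equal weight per class Crct1 was 2.08-fold lower and Cyp2a5 1.24-fold lower. Own clusters were looked at after these ratios were seen, for genes leading by level relative to the other clusters. Cyp2a5, Adh6a and Krt7 were among the leading genes of a cluster of 424 young and 94 old cells. Crct1 was among those of a cluster of 449 young and 212 old cells. Lce3a and S100a7a were among those of a cluster of 5 young and 43 old cells. How far such clusters account for the ratios was not tested. Crct1, Lce3a, Sprr1a and S100a7a lie on chromosome 3, in mm10 at 93014205 to 93015687, 92925287 to 92926230, 92483952 to 92485895 and 90654017 to 90658669. Krt16 lies on chromosome 11 at 100246091 to 100248902 and Krt4 on chromosome 15 at 101918535 to 101924735, both on the minus strand and both protein-coding. Hspa1a and Cyp2a5 have near-identical copies, and Adh6a, Ifit1bl1 and Lce3a have close relatives, so their counts could hold or lack reads of other genes. Hspa1b, the near-identical copy of Hspa1a, was 1.15-fold higher in the old library.

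Fewer genes were at least 2-fold higher than lower in the old library. Fxyd4, a regulator of the sodium pump, was at 36.8 CPM in the young and 92.0 CPM in the old library, 2.503-fold higher in old (2.43 to 2.58). Tsc22d3, a gene induced by glucocorticoids, was 1.97-fold higher, at 87.6 and 173 CPM. Gpha2, a glycoprotein hormone subunit and a marker of limbal cells, was 1.81-fold higher, at 150 and 271 CPM. The rule further named Ttc36 (1.79-fold), Ddah1 (1.77-fold), the retinal-oxidizing enzyme Aldh1a1 (1.73-fold), Gsta3 (1.57-fold), Wfdc2 (1.57-fold), Ide (1.56-fold), Cdo1 (1.53-fold), Aldh2 (1.51-fold) and the lipid carrier Apoe (214 and 322 CPM). Fxyd4 lies on chromosome 6 at 117933559 to 117937692, Tsc22d3 on chromosome X at 140539528 to 140600659 and Gpha2 on chromosome 19 at 6226380 to 6227768.

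Of 4839 genes compared over all cells, 5 were at least 2-fold higher and 19 at least 2-fold lower in the old library, and 92.5% lay closer to equal than the fold at which list members were counted as apart. The 5 higher genes were Fmo2 (3.57-fold, 3.36 to 3.798), Cyp2f2 (2.84-fold), Fxyd4, Pmepa1 (2.40-fold) and Timp3 (2.04-fold). All of these but Fxyd4 were outside the naming rule and were chosen after their values were seen. Among the genes 2-fold lower, Ly6d (6.30-fold) and Cnfn (4.05-fold) were named as list members, and 6 were chosen after their values were seen, namely Igfbp2 (2.37-fold), Ocm (2.33-fold), Cd274 (2.30-fold), Clic5 (2.16-fold), Chit1 (2.13-fold) and Krt23 (2.05-fold). Without the cluster of young cells alone Ly6d was 4.30-fold and Cnfn 3.03-fold lower, and with equal weight per class Cnfn was 2.34-fold, Clic5 1.42-fold and Cd274 1.33-fold lower. Ocm was among the leading genes of the cluster of 424 young and 94 old cells. Krt23 and Clic5 were among those of the cluster of 449 young and 212 old cells.

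The third comparison asked which genes differed within the epithelial classes, with each of the 7 classes given equal weight. Of 4835 genes, 7 were at least 2-fold higher and 16 at least 2-fold lower in the old library. Within own clusters in place of the authors' classes the counts were 4 and 9, and without the Conj class 3 and 10. Of the 7 and 16 genes, 4 and 13 were also 2-fold apart over all cells. Krt16 (11.3-fold) and Krt4 (4.63-fold) were lower in the old library in each of the 7 classes, as were AA467197 (2.69-fold), Ifit1bl1 (2.09-fold), Hspa1a (2.04-fold) and S100a7a (2.01-fold). For Krt16 and Krt4, free RNA from Conj cells stays open as a source of the counts in the other classes. Upp1, Arhgdib and Pbp2 were also named by the rule within classes, at 1.92-fold, 1.85-fold and 1.85-fold lower over all cells. Upp1 was among the leading genes of the cluster of 424 young and 94 old cells.

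Fxyd4 was higher in the old library in each of the 7 classes, 2.42-fold with equal weight. Tsc22d3, Gpha2, Aldh1a1, Gsta3 and Sorbs2 were higher in each class as well, with log2 ratios of 0.81, 0.72, 0.96, 0.73 and 0.68 at equal weight. The 7 genes at least 2-fold higher with equal weight were Fmo2 (3.31-fold), Krt8 (2.74-fold), Fxyd4, Cyp2f2 (2.24-fold), Pmepa1 (2.10-fold), Upb1 (2.07-fold) and Iqgap2 (2.00-fold), of which all but Fxyd4 were chosen after their values were seen. Krt8 and Krt18, partner keratins of simple epithelia, were both higher in the old library, Krt18 by 3.097-fold over all cells (2.96 and 9.16 CPM), while Krt13, a keratin of mucosal epithelia that was also chosen after its values were seen, was 2.02-fold lower with equal weight.

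**Figure D2:**
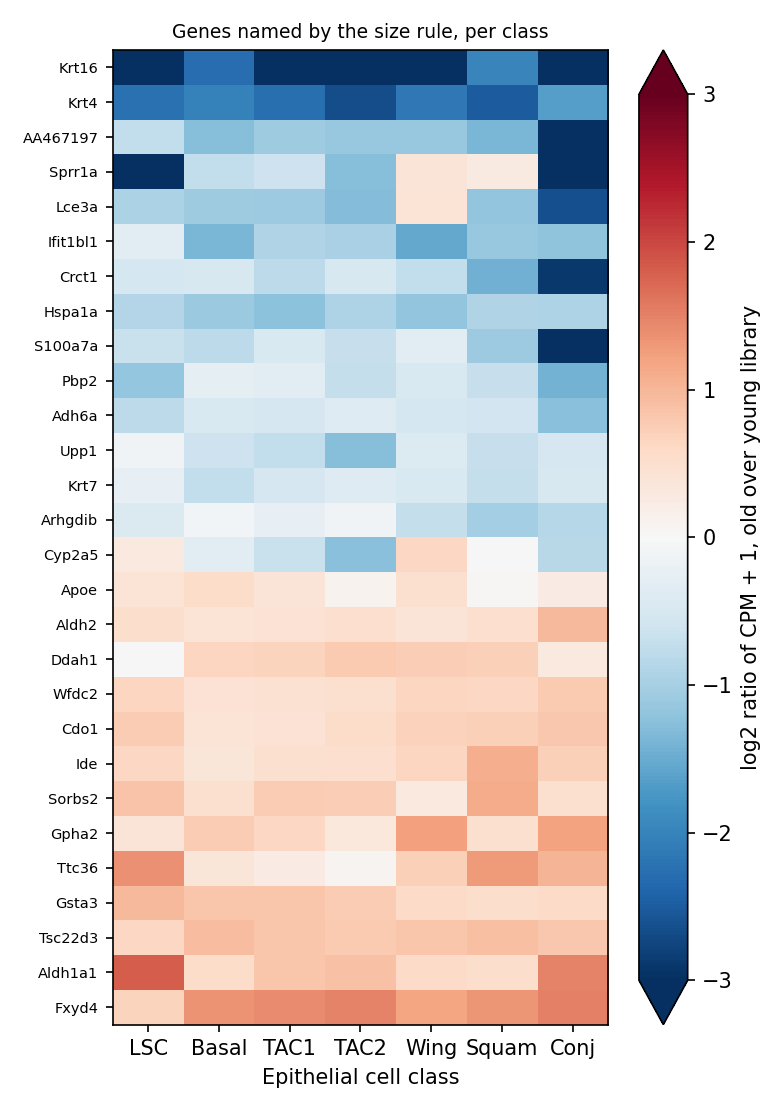
Log2 ratio of old over young CPM, with 1 CPM added, of each gene named by the rule within each epithelial class. Krt16 and Krt4 were lower and Fxyd4 and Tsc22d3 higher in the old library in each class shown.

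The same libraries were then compared by gene lists. Of 42 lists, 26 had 4 or more measured members, and 14 of them had a median outside the central 95% of random lists. For lists of independent genes 1.3 would be expected outside. By the mean over members 8 lists lay outside, and of simulated lists of unchanged genes 7.5% lay outside. Members of a list can move together, which neither the 1.3 nor the 7.5% allows for, so the count of 14 is a description only. Of these 14 medians, 6 were higher and 8 lower in the old library. Krt18, Rsad2, Usp18, Ifi44, Ddit3, Ocln, Hsph1, Dll1, Hmox1, Wnt11, Tfap2b, Areg and Cdkn2a are named with their lists, but were too low to enter the medians and counts. With equal weight per class 14 lists lay outside, and 11 of them did so both ways in the same direction.

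The conjunctival epithelium list was lower in the old library, with a median log2 ratio of -0.81 and 5 of 6 measured members counted as lower. Its members Krt4 and Krt7 are given above, Krt19 was 1.80-fold lower, and Krt18 was higher. The suprabasal and terminal differentiation list had a median of -0.37, of -0.20 without the cluster of young cells alone and of -0.22 with equal weight per class, and a mean over members of -0.98. Of its 7 measured members 4 were counted as lower, and Krt78 lay closest to equal (1.01-fold). Krtdap, too low to be counted among those 7, was 5.58-fold lower over all cells (2.56 and 0.459 CPM), a log2 ratio of -2.48 against -1.06 with equal weight per class. Sprr1b had 52 UMIs in the young and 0 in the old library, 14.0-fold lower by the floor of 3 counts over the library, with an exact lower bound of 10.99-fold. Its log2 ratio was -0.58 with equal weight per class.

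The interferon response list was lower over all cells (median -0.30, random lists -0.10 to 0.11) and higher with equal weight per class (0.26). Among classes with 4 or more members measured, the median was 1.19 in LSC, 0.0038 in Wing, -0.11 in Squam and -0.16 in Conj. The rise was thus outside the random range in LSC alone, and Squam and Conj lay below it. The all-cell median was -0.14 without the cluster of young cells alone, -0.16 as a mean over members, -0.12 from the mean of per-cell CPM and -0.09 with genes from 5 CPM included. Of its 10 measured members 1 was counted as higher and 5 as lower over all cells. Named members were on both sides, with Rsad2 (3.94-fold), Usp18 (2.20-fold), Ifi44 (1.80-fold) and Ifi27l2a (1.58-fold) higher in the old library, though the log2 ratio of Rsad2 was 1.98 over all cells and 0.43 with equal weight. Ifit3 (1.37-fold) and Isg15 (1.33-fold) were lower over all cells but higher with equal weight per class (log2 ratios of 0.33 and 0.32), and both were chosen after their values were seen. The list for antigen presentation by MHC class I was lower over all cells (-0.17), with Tap1 1.34-fold and Psmb8 1.31-fold lower and B2m 1.20-fold higher, and lay inside the random range with equal weight (-0.05).

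The immediate early response list was lower (median -0.18, and -0.25 with equal weight), with Ier3 1.81-fold, Dusp1 1.32-fold and Klf6 1.30-fold lower. Its members Fos, Jun and Egr1 were the leading genes of a cluster of 670 young and 388 old cells. The median was -0.52 in Basal, -0.29 in the single cluster that held the most Basal cells, and 0.18 in Squam. Cholesterol synthesis was lower by a median of -0.12, with Insig1 1.48-fold and Fdps 1.20-fold lower and 13 of 15 members with a log2 ratio below 0, of which 1 was counted as lower. Tight and gap junction genes were lower (-0.16), with Cldn7 1.45-fold and Ocln 1.33-fold lower and Gja1 1.30-fold higher. The unfolded protein response list was lower (-0.15), with Calr 1.18-fold and Pdia4 1.17-fold lower and Ddit3 1.38-fold higher.

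Lists higher in the old library were those of the mitochondrially encoded genes (median 0.22) and of ribosomal proteins (0.21). Of the mitochondrially encoded members 11 of 12 had a log2 ratio above 0 and 2 were counted as higher, and of the ribosomal members 82 of 84 had a log2 ratio above 0 and 10 were counted as higher. Ribosomal list genes took 23.5% of the old and 20.4% of the young library's UMIs. By class the shares in old and young were 31.9% and 30.8% in Basal, 15.7% and 12.5% in Conj and 7.53% and 6.86% in Squam. The mix of classes thus also enters the shares per library. With equal weight per class the median of the ribosomal list was 0.14. Members with a higher level in old included mt-Nd1 (1.36-fold) and mt-Nd3 (1.29-fold), and Rpl13a and Rps15 (both 1.34-fold). Rpl39l had 99 UMIs in the young and 0 in the old library, 26.7-fold lower by the floor, with an exact lower bound of 21.3-fold. Its log2 ratio was -0.47 with equal weight per class. Notch signalling genes were higher (0.20), with Dll1 1.56-fold and Jag2 1.23-fold higher and Nrarp 1.23-fold lower. Antioxidant and detoxification genes were higher (0.13), with Aldh1a1, Gclc (1.59-fold) and Sod1 (1.39-fold) higher, and Hmox1 1.80-fold lower. Wnt signalling genes were higher (0.14), with Wnt10a 1.28-fold and Sfrp1 1.26-fold higher and Wnt11 1.63-fold lower, though not outside the random range with equal weight (0.12). The heat shock list had a median of 0.14, with Hsph1 1.35-fold and Hspe1 1.20-fold higher, but a mean over members of -0.03, with Hspa1a 2.17-fold lower.

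**Figure D3:**
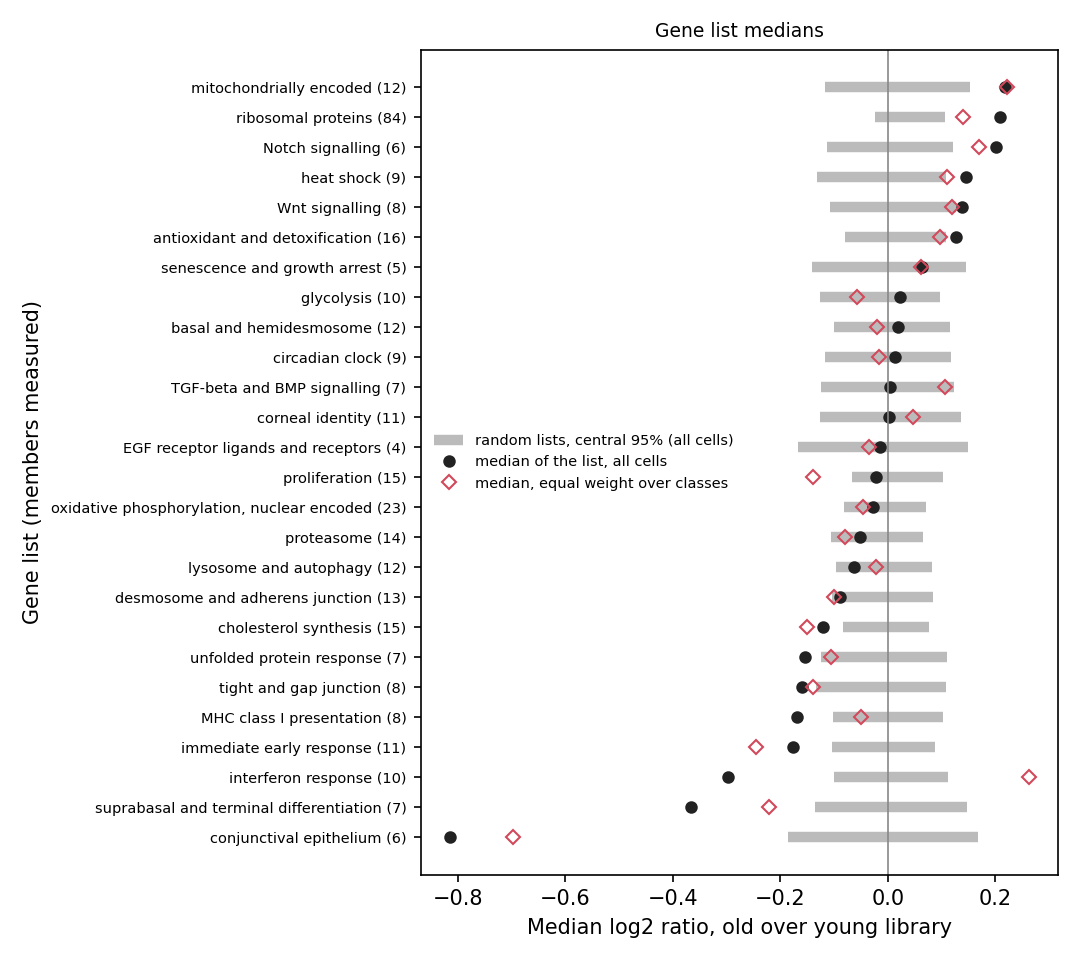
Median log2 ratio of old over young for each gene list with 4 or more measured members, over all cells and with equal weight per epithelial class, with the central 95% of random lists. The conjunctival epithelium list was lowest at -0.81, and the interferon response list lay on opposite sides, at -0.30 and 0.26.

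The other 12 lists lay inside the random range over all cells. Their medians were 0.06 for senescence and growth arrest, 0.02 for glycolysis, 0.02 for basal and hemidesmosome genes, 0.01 for the circadian clock, 0.00 for TGF-beta and BMP signalling, 0.00 for corneal identity, -0.02 for EGF receptor ligands and receptors, -0.02 for proliferation, -0.03 for nuclear-encoded oxidative phosphorylation, -0.05 for the proteasome, -0.06 for lysosome and autophagy and -0.09 for desmosomes and adherens junctions. With equal weight per class, proliferation (-0.14) and desmosomes and adherens junctions (-0.10) lay outside, both lower in the old library. Some members of the other lists lay far apart all the same. Cdkn2a, whose products include the cell cycle inhibitor p16, was 5.75-fold higher in the old library (4.96 to 6.69), at 1.17 and 6.73 CPM. Its log2 ratio was 2.52 over all cells, against 1.57 with equal weight per class. Counts per gene do not tell its transcripts apart. Hbegf and Areg, ligands of the EGF receptor, were 1.84-fold and 1.65-fold lower, Hbegf at 195 and 106 CPM, though with equal weight per class the log2 ratio of Hbegf was -0.29. Of the corneal identity genes, Slurp1 and Klf5 lay 1.001-fold and 1.003-fold apart, while Tfap2b was 1.72-fold higher and Elf3 1.20-fold lower in old.

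Lists with fewer than 4 measured members were summed instead. The limbal list summed to 5783 CPM in the young and 4594 CPM in the old library, with Krt15 1.31-fold lower and Gpha2 1.81-fold higher. Krt15 made up most of both sums, at 5531 and 4228 CPM. It was a leading gene of Conj, at 22258 CPM against a mean of 2872 CPM in the other classes. The sums thus also follow the share of Conj cells, which was smaller in the old library. The inflammatory and antimicrobial list summed to 341 and 291 CPM, with Nfkbia 1.57-fold lower, and MHC class II presentation to 56.2 and 41.4 CPM. Of the sex-linked list Xist alone was in the table, at 556 and 681 CPM. Lists for other cells were low in both libraries, as CPM in young and old: pan-leukocyte 7.78 and 6.17, macrophage, dendritic or Langerhans cell 10.1 and 7.19, T or NK lymphocyte 1.04 and 1.36, and neutrophil 6.17 and 1.18. Those of melanocytes (3.09 and 3.31 CPM), stromal fibroblasts (1.93 and 2.11), endothelium (0.209 and 0.326), Schwann cells (1.11 and 1.48), smooth muscle or pericytes (1.92 and 1.69), erythroid cells (0.666 and 0.498), lens (0.193 and 0.0598) and retina photoreceptors (1.18 and 1.24) were low as well.

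The fourth comparison asked how many epithelial cells were cycling. At equal depth, 11.955% of young cells (1233 of 10314; 11.3 to 12.6%) and 10.9% of old cells (1002 of 9176; 10.3 to 11.6%) carried at least 2 of the 9 cell cycle markers, a difference of -1.03 points (-1.93 to -0.13). With at least 1 marker the thinned difference was -1.10 points, with an interval that held 0 (-2.28 to 0.0727). With at least 3 markers it was -0.814 points (-1.60 to -0.0295). Among unthinned cells the shares were 17.8% and 15.7%, a difference of -2.15 points. In the Basal, TAC1, TAC2 and LSC classes together the thinned shares were 22.5% and 18.1%, a difference of -4.40 points (-5.98 to -2.82). Basal cells, of which few were cycling, made up 2452 of these 5014 young and 2729 of these 5139 old cells, so the pooled difference also holds the mix of classes. Within classes, the shares were 14.3% and 6.72% in LSC, a difference of -7.56 points (-12.5 to -2.78). For TAC2 (89.6% and 87.5%), TAC1 (21.3% and 18.9%) and Basal (1.55% and 1.28%) the interval of the difference held 0. It also held 0 for Wing (1.43% and 1.17%) and for Conj, where the share was higher in old (4.76% and 6.14%). In the Squam class, whose outer cells should hold few dividing cells, the share was 1.16% in young and 1.17% in old, with median depths of 19136 and 15909 UMIs before thinning. Of the LSC cells 51.5% of the young and 78.3% of the old fell in the same single cluster, so the LSC class was not made up alike at the 2 ages.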

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

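In this part the values within single clusters were computed only after the results were seen, as was the test of the 1% of cells as the source of the interferon split, and the other tests on the interferon list were fixed before their results were seen. The lists below lay outside the range of random lists on the high side in at least 1 epithelial class and on the low side in at least 1 other. The classes given are those outside with the highest and the lowest median, and for each list further classes lay outside as well. These differences between classes were not tested. TGF-beta and BMP signalling had a median log2 ratio of 0.41 in LSC and -0.17 in TAC1, and of 0.19 in the leading cluster of LSC cells. Cholesterol synthesis had a median of 0.13 in Basal and -0.62 in LSC, but of 0.37 in the leading Basal and 0.52 in the leading LSC cluster. Proliferation had a median of 0.37 in Conj and -0.38 in LSC, and of 0.13 in the leading Conj and -0.64 in the leading LSC cluster. Interferon response had a median of 1.19 in LSC and -0.16 in Conj, and a positive median in both leading clusters, at 1.04 for LSC and 0.22 for Conj, the latter over 5 measured members against 10 in the Conj class. Medians in a class and in its leading cluster rest on members measured in each, which are not all the same. The Conj class was made up of different clusters at each age, since its second cluster held 36.8% of young and 16.4% of old Conj cells and the cluster of young cells alone held 130 young and 0 old Conj cells. The Basal class was also made up differently, with 22.4% of young and 12.2% of old Basal cells in 1 of its clusters, whose leading genes were Fos, Jun and Egr1.

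The interferon response list was lower in the old library over all cells and higher with equal weight per class, at medians of -0.30 and 0.26. With the young library's share of UMIs per class given to both libraries, the all-cell median was -0.1214, between the values that would have argued for and against a different mix of classes, so a mix may account for part of the split and stays open. Without the 1% of cells with the most interferon UMIs in each class and library, the medians were -0.40 and 0.16, a largest move of 0.1013, and the difference between them kept 100.5% of its size, so these cells are not the source of the split, while other small sets of cells stay open. In the LSC class the median was 0.61 without those cells, the top 5% of cells held 36.9% of the list's UMIs in the old and 21.4% in the young library, and Ifit1 was found in 36 old and 6 young cells. A difference with age stays open and was not tested, since each age had 1 library.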

How the results depend on the processing

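In this part the repeats without the Conj class, without the cluster of young cells alone, without high Scrublet scores, with a ribosomal list without the kinases, and with clusters made without the genes apart were chosen after seeing the data. With the other scalings, the cell filter and thinned cells, each count of genes at least 2-fold apart stayed within 1.5 times its main value. Counts followed the minimum level, since it sets which genes are compared. At 50 CPM, 1 gene was higher and 11 lower in old over all cells, and 1 was higher within classes. At 5 CPM, 18 were higher and 43 lower over all cells, and 18 were higher within classes. A pseudocount of 5 CPM, which draws low genes toward equal, gave 3 higher and 11 lower over all cells, and 2 higher and 6 lower within classes. Within own clusters 4 were higher and 9 lower, and without the Conj class 3 were higher and 10 lower within classes. Own clusters gave share differences of 3.50 points for Basal, 2.56 for LSC, -1.96 for Squam and, with the direction reversed, 0.70 for Wing. Clusters made without the genes apart gave 6.60 for Basal, -2.61 for Conj, 2.62 for LSC, -1.78 for Squam and -3.87 for Wing. Conj was at -2.75 without the cluster of young cells alone. The cycling difference was -2.15 points in unthinned cells and -4.40 in the basal classes only. By the mean over members 8 lists lay outside the random range and the heat shock list turned to -0.030. Equal weight per class turned the interferon list to 0.26. Except where the construction shows it, the cause was not tested. Of 384 repeats of named genes none reversed and 251 moved beyond their counting interval, and of 209 repeats of list medians 2 reversed, both given here, and 15 moved. The repeat without called doublets was not run, and with 1 library per age no result has a replicate behind it.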

Other observations

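In this part the tests on fewer Conj cells, on the cells with the most Krt16 UMIs as the whole cause and on the mix of classes for the clock genes, the values within single clusters, the genes named per class, and the clock genes other than Arntl, Cry1, Nr1d1, Ciart, Nr1d2 and Tef were chosen only after the results were seen. The LSC class held the most genes at least 2-fold apart, 73 higher and 41 lower in old among 5396 genes, and 74 and 41 at an equal sum of UMIs per class, against 49 and 51 in Conj at that sum. The antiviral gene Ifit1 was at 1.45 CPM in young and 53.7 CPM in old LSC cells, where 23 cells held 95.2% of its UMIs. The iron-binding protein gene Lcn2 was at 6.27 and 60.5 CPM, Isg15 at 10.1 and 50.9, Ccn2 at 21.2 and 102, and Fmo2 at 40.7 and 168. Marker sets of other cells went both ways in old LSC cells. Myeloid markers were at 3.62 and 31.1 CPM, but most of the old sum was Cd74, a member of that set, at 2.17 and 21.8 CPM. Smooth muscle or pericyte markers were at 5.54 and 14.4 CPM and the stromal fibroblast marker at 7.96 and 13.0 CPM. Markers of T or NK lymphocytes (1.21 and 0.399 CPM) and of melanocytes (3.62 and 2.79 CPM) were lower in old. Lower in old LSC cells were Krtdap (18.2-fold), Sprr1a (12.6-fold), Krt16 (10.2-fold), Krt13 (5.81-fold) and Krt4 (4.76-fold). The makeup of the class differed, since its leading cluster held 188 of 365 young and 350 of 447 old LSC cells. Within it 87 genes were at least 2-fold higher and 23 lower in old, counted with 1 CPM added and no condition on the interval. The class counts above had no CPM added and needed an interval that excluded 1, so they cannot be set against these. Within that cluster Ifit1 (1.02 and 57.5 CPM), Isg15 (5.39-fold), Lcn2 (6.43-fold) and Fmo2 (2.98-fold) were again higher in old, while Krt16 was 2.20-fold higher in old (1.40 to 3.62), Krt13 and Krt4 were 1.76-fold and 1.44-fold lower, and the intervals of Krtdap and Sprr1a held 1.

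In the Squam class the genes lower in old included Lce3b (7.03-fold), Bambi (6.37-fold), Tnf (4.63-fold) and the NF-kappa-B inhibitor Nfkbia (3.41-fold), and Ttc36 (2.44-fold) and Txnip (2.33-fold) were higher. The makeup of the Squam class also differed, since its leading cluster held 56.5% of young and 66.4% of old Squam cells and its second 30.1% and 16.5%. Within the leading Squam cluster Bambi was 3.71-fold lower, Ttc36 2.19-fold and Txnip 2.13-fold higher in old, while Nfkbia was 1.32-fold higher in old and the intervals of Lce3b (7 and 1 UMIs) and Tnf (5 and 3 UMIs) held 1. In the Conj class Krt18 was 10.3-fold and Id3 4.81-fold higher in old, and Krt14 was 3.27-fold lower, against 8.93-fold, 3.74-fold and 3.26-fold in the leading Conj cluster. Igfbp2, a binding protein of insulin-like growth factors, was 11.7-fold lower in old TAC1 cells, 7.42-fold lower in TAC2, 6.85-fold lower in Basal and 1.76-fold lower in LSC, but at 8.25 and 9.55 CPM in Conj, with an interval of the ratio that held 1. Within the leading cluster of each class Igfbp2 was 7.13-fold lower in TAC1, 7.25-fold in TAC2 and 8.21-fold in Basal. The TAC1 class too was made up differently, with 52.1% of young and 64.1% of old TAC1 cells in the leading TAC1 cluster. Cdkn2a was 4.65-fold higher in old TAC2 cells, at 6.09 and 28.3 CPM, and 5.77-fold higher within the leading TAC2 cluster. In the Immune class, markers of T or NK lymphocytes had 3 UMIs among 65 young cells and 60 among 42 old cells, but 1 young and 5 old cells held 2 or more of them (1.54%, 0.0389 to 8.28%, and 11.9%, 3.98 to 25.6%), and myeloid markers summed to 41081 and 31164 CPM.

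Krt16 and Krt4 were lower in old in each of the 7 epithelial classes. Fewer Conj cells do not account for the difference within the Conj class, where Krt4, the nearer to equal of the pair, had a log2 ratio of -1.652. That ratio does not bear on free RNA from Conj cells in the other classes. A small subset of cells may account for part of the Krt16 difference, since 2% of the young cells held 90.15% of its UMIs, and 76.0% of these cells were Conj. The UMIs counted in such cells are not the whole cause, since without these cells Krt16 and Krt4 still had log2 ratios of -2.40 and -2.271. Leaving cells out does not remove free RNA that they may have shed into others. Free RNA from Conj cells stays open for the other classes. The level in Basal relative to Conj lay low among 266 genes high in Conj, at percentile 1.504 for Krt4 and lower for Krt16. Those 266 genes had a median level in Basal of 3.84% of that in Conj in the young library, and Basal cells may express some of them. A low share therefore could not count against free RNA. A difference with age was not tested. In Basal, Krt16 was at 0.283% of its Conj level in young and 0.260% in old, and Krt4 at 0.439% and 0.267%.

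Some clock genes lay apart in opposite directions, with Arntl 3.24-fold (a log2 ratio of 1.69, and of 0.92 with equal weight per class), Cry1 1.45-fold and Clock 1.21-fold higher in old and Nr1d1 1.37-fold, Ciart 1.44-fold, Dbp 1.29-fold and Per1 1.23-fold lower, while Hlf was 1.18-fold higher and Per2, Per3, Nr1d2, Tef and Cry2 lay at most 1.04-fold apart. A different mix of classes does not account for this. The difference between the 3 higher and the 4 lower genes kept 87.43% of its all-cell size with equal weight per class. Arntl was at 1.05 CPM in young and 3.39 CPM in old, on 195 and 510 UMIs. Cry1 (6.04 and 8.73 CPM), Ciart (7.64 and 5.30 CPM) and Per1 (19.5 and 15.8 CPM) were low as well. All of these lay under 20 CPM in both libraries and entered neither the median nor the counts of the clock list. Nr1d1 (62.0 and 45.3 CPM), Dbp (199 and 154 CPM) and Clock (40.2 and 48.7 CPM) lay above that level. A different phase of the clock when the corneas were taken was tested on 4 further clock-controlled genes, and 1 of the 4, Nfil3, lay in the predicted direction, on 23 and 34 UMIs. Usp2 and Nampt lay against it, with log2 ratios of 0.26 and 0.37, and the interval of Wee1 held 1 (0.959 to 1.05). By the criterion fixed beforehand, at most 1 of 4 in the predicted direction counted against a different phase. The count of 1 met that criterion. It made no allowance for Wee1 being undecided, with which the count could be 1 or 2 of 4. The time of sampling is not given in the sources used here, so a different phase cannot be told apart from an age difference.

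Tsc22d3 and Fxyd4 were higher in old in each epithelial class, and a stronger glucocorticoid response might raise both. The median log2 ratio of 4 measured further glucocorticoid targets was -0.076, inside the range of random lists (-0.18 to 0.15). By the criterion fixed beforehand, a median inside or below that range counted against a stronger glucocorticoid response, and the median met that criterion. Fkbp5 (0.13) and Glul (0.05) were higher and Sgk1 (-0.22) and Errfi1 (-0.21) lower, so the members lay on both sides of 0. The criterion made no allowance for this, and the median of 4 members alone does not exclude the hypothesis.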
